A study of Mus musculus with 12 samples.

How the data were processed

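Mature miRNAs were measured with a NanoString nCounter mouse miRNA panel in immortalized mouse macrophages (IMM), a macrophage line kept in permanent culture. Per the labels, cells were stimulated with lipopolysaccharide (LPS, a component of the outer wall of Gram-negative bacteria that activates macrophages) at 100 ng/mL for 30, 60 or 120 min. The 0 min samples were named as the control, and each of the 4 time points had 3 biological replicates, 12 samples in total. The labels describe growth in DMEM with 10% serum and 0.02 M HEPES at 37 °C and 5% CO2, dishes of 10 cm, 2 washes with PBS on ice, and RNA extraction with a miRNeasy kit.

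The deposited table holds 626 probes: 566 for mouse miRNAs, 33 for miRNAs of mouse herpesviruses, and 27 for other targets. The other targets include 6 positive and 8 negative hybridization controls, 3 positive and 3 negative ligation controls, and 4 housekeeping mRNAs (Actb, B2m, Gapdh, Rpl19). In this assay a tag is ligated to each miRNA before hybridization, and the ligation controls are added RNAs that report on that step. How the authors normalized the counts is not given in the sources used here. The unit of the deposited values is therefore called signal, and its scale was read from the values themselves. Every sample's signal above 20 and below 2000 was a whole multiple of 1 step per sample within 0.1 of a step (100% of values). The steps ran from 0.748 to 2.26 signal units. The geometric mean of the 4 housekeeping mRNAs was 9390.3 in all 12 samples, and no miRNA lay under a floor of 20. The deposited signal thus has the form of counts multiplied by 1 factor per sample, with a floor of 20 applied. The positive and negative hybridization controls held whole counts without a factor. At its floor a sample with a large step hides more signal, and in 0 min replicate 1 a floored entry can stand for up to 45.3.

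Depth was read by dividing the signal above the floor by each sample's step. It ran from 138655 to 365403 counts per sample over all such probes, and from 114754 to 313170 counts over mouse miRNAs. The mean of the negative controls ran from 8.38 to 14.4 counts per sample. The highest negative control of a sample ran from 24 to 36 counts, and was 32 counts in 0 min replicate 1, which has the largest step. Signal near the floor is therefore not clearly above background. Between 148 and 267 mouse miRNAs lay above the floor in a sample, and 263 (46.5%) lay at the floor in all 12 samples. For these 263 a difference was not detectable at this depth.

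The comparisons used log2 of the signal plus a pseudocount of 1. Mouse miRNAs were tested when their mean over the 12 samples exceeded the mean plus 2 SD of the negative controls (30.5), which kept 166 and left out 400. The negative controls are counts without a factor, so this threshold was set against signal in an unlike unit. In counts it differs between samples by their steps. A linear model with 1 mean per time point was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided tests, 8 residual degrees of freedom). The contrasts tested were each stimulated time point against 0 min, 60 against 30 min, and 120 against 60 min. A moderated F test covered the 3 contrasts against 0 min together. P values were adjusted by the Benjamini-Hochberg method over the 166 miRNAs of each contrast, with a threshold of 0.05. The fit estimated the same variance for every miRNA, so that all standard errors of a log2 change equal 0.378. Its tests thus pooled the residuals of the 166 miRNAs and used far more than 8 degrees of freedom. These residuals share sample-wide factors (0.62 to 1.71 for the 100 most abundant miRNAs) and are not independent. Very small p values therefore overstate what 3 against 3 samples can show. Fold changes are given as log2 fold change ± SE unless said otherwise, and group values as mean signal ± SD with 3 replicates per time point.

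The model, filter, contrasts, miRNA lists, the rule for naming miRNAs and most alternatives were fixed before the data were examined. The naming rule took, for each time point against 0 min, up to 15 passing miRNAs with the largest rise and up to 15 with the largest fall. Where fewer than 10 passed, it added the 5 highest and 5 lowest log2 changes with an unadjusted p under 0.05. It also took every tested miRNA of the LPS-induced list, up to 4 members of each other list and the 5 most abundant miRNAs. MiRNAs outside this rule are said where they appear to have been chosen after their values were seen.

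Of the 21 lists, 12 had at least 3 tested members and were tested with camera (limma, preset correlation 0.01) for the 3 contrasts against 0 min, which gives 36 tests adjusted together. Camera with an estimated correlation and fry were run beside it. The lists tested were the let-7 family, the miR-99b/let-7e/miR-125a cluster with its paralogs, miR-17~92 with its paralogs, miR-15/16, miR-23/27/24, miR-29, miR-30, miRNAs abundant in myeloid cells, epithelial markers, mesenchymal and endothelial markers, the Dlk1-Dio3 cluster and the Sfmbt2 cluster. LPS-induced miRNAs, miR-181, miR-221/222 and neural markers had 1 or 2 tested members, and are described only. Lymphoid and erythroid, muscle, liver and stem cell markers and stress-related miRNAs had none. A list entry matched a probe of that name with or without an arm suffix. The probe named miR-21 carries the older name of miR-21a. It did not match the LPS-induced list or the myeloid list, which both hold miR-21a, so its value is given separately.

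The alternatives planned were no filter, a filter at a mean of 100, a pseudocount of 10, scaling to the geometric mean of the 100 most abundant miRNAs (called top-100 scaling here), quantile normalization, median scaling, eBayes with trend and robust estimation, only the 2 compared time points in the fit, the replicate number as a block, and leaving out each of the 12 samples in turn. Scaling to the 3 ligation positive controls, 1 common floor of 45.3 in all samples, the common floor with top-100 scaling, fits without 0 min replicate 1 or without the first replicates of 0 and 120 min, list tests leaving out each sample with the 166 miRNAs kept, and the summed signal without each sample were added after seeing the data. In the common floor with top-100 scaling, the floor was set before the division by the sample factor. Entries at the floor then differ by these factors alone, which lowers the change of a miRNA floored at 0 min. A negative sign there is not evidence of a fall. Alternatives for raw counts (other count-based scalings, and scaling to the positive controls with negative controls subtracted) had been chosen too but were not run, because the deposited values are normalized. The overall level per sample was compared by exact two-sided permutation tests, for which 3 against 3 samples cannot give a p below 0.1.

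The fit was tested on simulated data, in 20 simulations of 166 miRNAs with normal noise, using each miRNA's mean and its residual SD after top-100 scaling, and changes planted at 120 min. A planted log2 change of 1 was recovered for 89.8% of miRNAs and of 2 for 100%, with 1.15 false calls on average among 126 unchanged miRNAs. With the sample-wide factors shuffled over the 12 samples and added, recovery was 35.8% and 99.8%, with at most 12 false calls. The shuffling breaks any link of the factors with time, and the simulation had no floor. These false calls therefore do not measure what a shift that goes with time would give. The numbering of replicates was checked by correlating the residuals across miRNAs. Of 18 same-number pairs 5 had a correlation above 0.1, and 5 of 12 samples correlated best with a sample of their own number. Such a correlation leaves out the level of a whole sample, so it cannot show a level shared by number. The samples were kept unpaired, as fixed beforehand. Positions are from the RefSeq annotation of the GRCm38.p6 mouse assembly, since the labels give no build. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Viral, control and housekeeping probes were left out of the miRNA tests, and the 9 probes that name several miRNAs were kept as 1 value each.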

Results

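Immortalized mouse macrophages were profiled for miRNAs before and after LPS, with 3 biological replicates at each of 0, 30, 60 and 120 min. Depth ran from 138655 to 365403 counts per sample, with the lowest in 0 min replicate 1. The most abundant signal came from the probe shared by miR-20a and miR-20b, members of the growth-promoting miR-17~92 family, which held 9.64% of the miRNA signal (mean 20772 ± 6795, SD, n = 12). Let-7g followed with 6.41% and 13823 ± 3865. MiR-720, a name now given to a tRNA fragment, held 6.23%, let-7a 5.85%, and the probe shared by miR-106a and miR-17 4.88%. The 5 most abundant probes held 33.0% of the signal and the 20 most abundant 76.1%. Among miRNAs typical of myeloid cells, miR-142-3p averaged 8873 ± 4801 and miR-146a 3684 ± 1800 over the 12 samples.

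The signal of most miRNAs was higher in stimulated than in 0 min samples on the deposited scale, and this shift stands behind every comparison that follows. The median log2 change of the 166 tested miRNAs was 0.28 at 30 min, 0.43 at 60 min and 0.57 at 120 min, with positive changes for 80.1%, 81.3% and 80.7% of them. Under top-100 scaling the medians were -0.06, -0.03 and -0.06. Under scaling to the ligation controls, an alternative chosen after seeing the data, they were -0.52, -0.38 and -0.18. The ligation controls, added RNAs that the cells do not make, gave 17.9, 36.0 and 36.1 counts per 1000 positive control counts in the 0 min samples. All 9 stimulated samples lay higher, between 50.8 and 75.1 (exact permutation test, two-sided, p = 0.00455, adjusted p = 0.0864 over 19 tests of overall levels). This test of 9 against 3 samples was not planned, and its p is the smallest that it can give. Summed miRNA signal differed from 0 min by 0.20, 0.28 and 0.43 log2 units at 30, 60 and 120 min (exact p = 0.6, 0.5 and 0.4, adjusted p = 0.671, 0.594 and 0.543), and without 0 min replicate 1 by 0.49, 0.57 and 0.72. Without 0 min replicate 3 it differed by -0.00287 at 30 min and 0.08 at 60 min, and without 120 min replicate 1 by 0.17 at 120 min. The library of 0 min replicate 1 had 178.8 housekeeping counts per 1000 positive control counts, against 544.8 and 513.7 in the other 0 min samples. Changes below are on the deposited scale unless another scaling is named, and so include this shift.

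**Figure D1:**
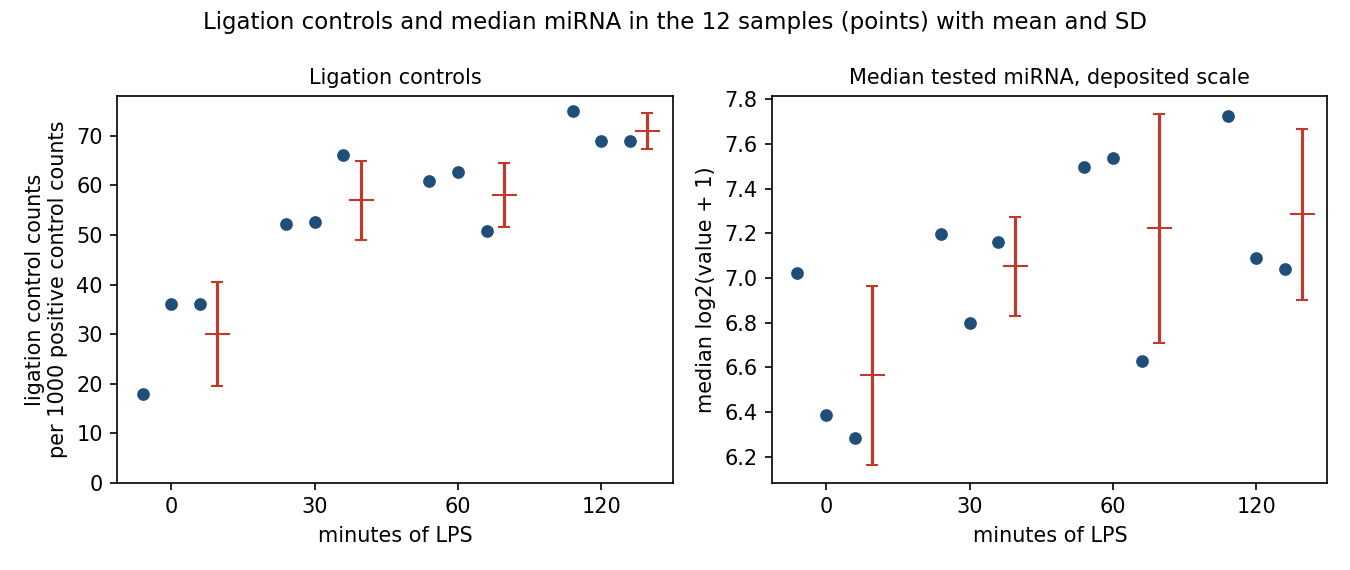
The left panel plots ligation control counts per 1000 positive control counts and the right panel the median log2 signal of the tested miRNAs, against minutes of LPS, with 1 point per sample and the mean ± SD in red. The 3 samples at 0 min lie between 17.9 and 36.1 in the left panel and all 9 stimulated samples between 50.8 and 75.1.

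The 30 min comparison addressed the earliest change in the expressed miRNAs after LPS. MiR-376a, from the imprinted Dlk1-Dio3 cluster (chromosome 12, 109723781 to 109723848), rose from a signal of 53.2 ± 20.1 (SD, n = 3) to 180.9 ± 83.1, a log2 change of 1.72 ± 0.38. MiR-125a-3p, the passenger arm of the miR-125a precursor, rose from 39.7 ± 26.5 to 114 ± 57.7 (1.58 ± 0.38). MiR-3099 rose from 21.5 ± 2.67, with 2 of its 3 samples at the floor, to 65.4 ± 16.7 (0.49 under a common floor of 45.3 in all samples, an alternative chosen after seeing the data). MiR-760 rose from 76.7 ± 43.1 to 184 ± 53.9 (1.39 ± 0.38) and miR-2135, with 1 of 3 samples at the floor at 0 min, from 30.3 ± 10.8 to 78.6 ± 19.5 (0.75 under the common floor). The signal of all 5 was higher in 3 of 3 samples than in any 0 min sample, an order that chance gives to at most 5% of miRNAs and that 26 of the 166 tested showed. MiR-142-3p, a marker of blood-forming lineages, had 3937 ± 1717 at 0 min and 8563 ± 3129 at 30 min and did not pass (adjusted p = 0.0651).

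These 5 miRNAs, all higher, passed in limma at adjusted p between 0.00097 and 0.0097, and 21 had an unadjusted p under 0.05. Relative to the median shift the log2 changes were 1.44 for miR-376a, 1.29 for miR-125a-3p and 1.11 for miR-760. None of the 5 passed under the common floor (adjusted p from 0.523 to 0.736), where miR-376a, miR-760 and miR-125a-3p, which had no floored sample at 0 min, had changes of 1.58, 1.25 and 1.00. The variance estimates of the fit differ there too, so a lost call alone does not show dependence on floored signal. None passed under top-100 scaling (1.38, 1.05 and 1.25 for the same 3), where miR-22 alone passed, lower by a log2 change of -0.80 ± 0.15 (0 higher and 1 lower, with 55 at an unadjusted p under 0.05). Scaling to the ligation controls gave 2 higher and 79 lower. Without 0 min replicate 2 or without 30 min replicate 3 the deposited scale gave 0 calls, with changes of 1.43 and 1.37 for miR-376a, 1.30 and 1.19 for miR-125a-3p and 0.90 and 1.17 for miR-760. Without 30 min replicate 1 it gave 3, with miR-760 (1.42) and miR-2135 no longer passing, and without 0 min replicate 1 miR-2135 did not pass.

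At 60 min the same direction held for more miRNAs. MiR-376a rose to 516 ± 248, a log2 change of 3.22 ± 0.38 from 0 min (adjusted p = 7.25e-15), or 2.79 above the median shift. Over the alternatives its adjusted p in limma reached 0.0522. MiR-760 rose to 344 ± 127.6 (2.27 ± 0.38), miR-3099 to 116 ± 61.3 and miR-125a-3p to 167 ± 79.6 (2.09 ± 0.38). MiR-142-3p rose to 12292 ± 3141 (1.70 ± 0.38) and miR-1902 from 93.8 ± 23.1 to 265 ± 81.2 (1.46 ± 0.38). MiR-691, at the floor in all 3 samples at 0 min, reached 73.4 ± 19.9, a mean 1.62 times the 45.3 that the floor can hide. The 3 samples of miR-376a, miR-760, miR-3099, miR-125a-3p, miR-142-3p, miR-1902 and miR-691 at 60 min each lay above every 0 min sample. Under the common floor only miR-376a and miR-760 passed at 60 min (3.08 and 2.13). MiR-691 (0.65, adjusted p = 0.217; 0.19 with top-100 scaling added, adjusted p = 0.642) and miR-3099 (1.22, adjusted p = 0.133; 0.75, adjusted p = 0.128) did not pass under either. MiR-125a-3p, miR-142-3p and miR-1902 (1.51, 1.70 and 1.46) did not pass under the common floor alone and passed with top-100 scaling added (1.05, 1.22 and 0.99). For miR-142-3p and miR-1902 the change under the common floor equals that on the deposited scale. Their calls ended there through the variance estimates of the fit and not through signal hidden by the floor.

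In limma 18 miRNAs passed at 60 min, 18 higher and 0 lower, and 39 had an unadjusted p under 0.05. Of the 18, 16 had all 3 samples above every 0 min sample, as had 30 of the 166 tested. The other passing miRNAs within the naming rule were miR-490, miR-21 and miR-136 (1.21, 1.14 and 1.13; 0.74, 0.67 and 0.66 under top-100 scaling, all passing), and miR-32, miR-2135, miR-2183, miR-3471 and miR-701. Of the last 5, miR-32 and miR-2135 had 1 of 3 samples at the floor at 0 min, miR-2183 had 2, and miR-3471 and miR-701 had 3. Their changes under the common floor were 0.95, 0.74, 0.29, 0.46 and 0.20, and none passed there. With top-100 scaling added, miR-3471, miR-701 and miR-2183 turned slightly negative (-0.00, -0.26 and -0.17). For floored entries this sign comes with setting the floor before the scaling and is no evidence of a fall. Top-100 scaling gave 19 higher and 33 lower, and ligation control scaling gave 7 higher and 62 lower. Without 0 min replicate 1, an alternative chosen after seeing the data, top-100 scaling gave 9 higher and 14 lower. Of the 18 higher on the deposited scale, 13 were also higher under top-100 scaling and 7 under all 3 scalings. MiR-22, a widely expressed miRNA chosen after its values were seen, had a log2 change of -0.48 ± 0.38 on the deposited scale and did not pass; it was lower by -0.95 ± 0.15 under top-100 scaling.

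The 60 min count depended on single libraries. It was 38 without 0 min replicate 1 and 41 without 60 min replicate 3, and 10, 9, 10 and 7 without 0 min replicate 2, 0 min replicate 3, 60 min replicate 1 and 60 min replicate 2. The calls of miR-376a, miR-760, miR-3099, miR-125a-3p, miR-142-3p and miR-691 passed without any one of the 12 libraries, whereas miR-1902 ended without 60 min replicate 2 (log2 change 1.28). With no filter, where 566 miRNAs were tested, 0 passed at 60 min, so these calls ended too. Of the weaker calls, miR-32 ended without 0 min replicate 3, and miR-3471 and miR-2135 without 60 min replicate 2. MiR-490 and miR-701 ended without any one of 0 min replicates 2 and 3 and 60 min replicates 1 and 2 (lowest value 1.01 for miR-490). MiR-21, miR-136 and miR-2183 ended without any one of those or without 30 min replicate 1 or 3 (lowest values 0.93 for miR-21 and 0.95 for miR-136).

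By 120 min the response was led by the same miR-376a, which reached 1089 ± 269.9, a log2 change of 4.37 ± 0.38 (adjusted p = 2.88e-27). Over the alternatives its adjusted p in limma rose to at most 0.0018. MiR-760 (chromosome 3, 122293585 to 122293703) reached 623 ± 86.3 (3.17 ± 0.38) and miR-3099 (chromosome 7, 6803587 to 6803670) reached 193.7 ± 50.4 (2.04 under the common floor). MiR-691, at the floor in all 0 min samples, reached 127.2 ± 32.6, a mean 2.81 times the 45.3 that the floor can hide. MiR-1902 rose to 353 ± 86.3 (1.90 ± 0.38), miR-490 from 52.4 ± 17.9 to 167 ± 38.6 (1.68 ± 0.38), and miR-103, a miRNA linked to insulin sensitivity, from 379.5 ± 90.9 to 1073 ± 201 (1.51 ± 0.38). The calls of these 7 passed under each of the alternatives that gave them a value. Relative to the median shift their log2 changes ran from 0.93 for miR-103 to 3.79 for miR-376a.

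MiR-1970, miR-701, miR-92a, miR-3471, miR-301b and miR-222 were at the floor in all 3 samples at 0 min. The mean signal at 120 min of miR-1970, miR-701 and miR-92a was 2.20, 1.72 and 1.26 times the 45.3 that the floor can hide. For miR-3471, miR-301b and miR-222 (means 56.8, 56.9 and 47.0) the lowest 120 min samples, 42.3, 41.9 and 42.7, lay below 45.3. Under a common floor combined with top-100 scaling the changes of miR-92a, miR-3471, miR-301b and miR-222 turned negative (-0.31, -0.30, -0.31 and -0.54) and did not pass. Floored entries are divided by unlike sample factors there, so this sign is no evidence of a fall. MiR-466h rose from 20.4 ± 0.71 to 80.4 ± 23.3 and miR-2183 from 21.3 ± 2.18 to 72.4 ± 14.3, each with 2 of 3 samples at the floor at 0 min. Under the common floor miR-1970, miR-701 and miR-466h passed (1.09, 0.73 and 0.77) and miR-2183 did not (0.65, adjusted p = 0.0565). With top-100 scaling added, none of miR-1970, miR-701, miR-466h and miR-2183 passed (0.46, 0.11, 0.14 and 0.02), nor did miR-764-3p (0.34). MiR-764-3p, with 1 of 3 samples at the floor at 0 min, rose from 41.5 ± 24.3 to 103 ± 18.6 (0.97 under the common floor), a call that ended without 0 min replicate 2. MiR-125a-3p had 64.8 ± 16.1 and miR-2135 had 55.9 ± 22.2 at 120 min, and neither passed against 0 min there (both at adjusted p = 0.082).

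Across the 166 miRNAs, 36 passed at 120 min in limma, 36 higher and 0 lower, and 64 had an unadjusted p under 0.05. Of the 36, 33 had all 3 samples above every 0 min sample, as had 58 of all tested. Top-100 scaling gave 24 higher and 45 lower, and ligation control scaling 15 higher and 48 lower. Top-100 scaling gave 18 higher and 28 lower without 0 min replicate 1, and 18 higher and 22 lower without the first replicates of 0 and 120 min. All 24 were among the 36, 15 of the 36 were higher under all 3 scalings, and 45 were lower under both top-100 and ligation control scaling. Where one of the 45 had floored samples, the division of floored entries by the sample factors enters its change. The count was 81 without 0 min replicate 1, 21 without 0 min replicate 2, 19 without 0 min replicate 3 and 16 without 120 min replicate 1.

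**Figure D2:**
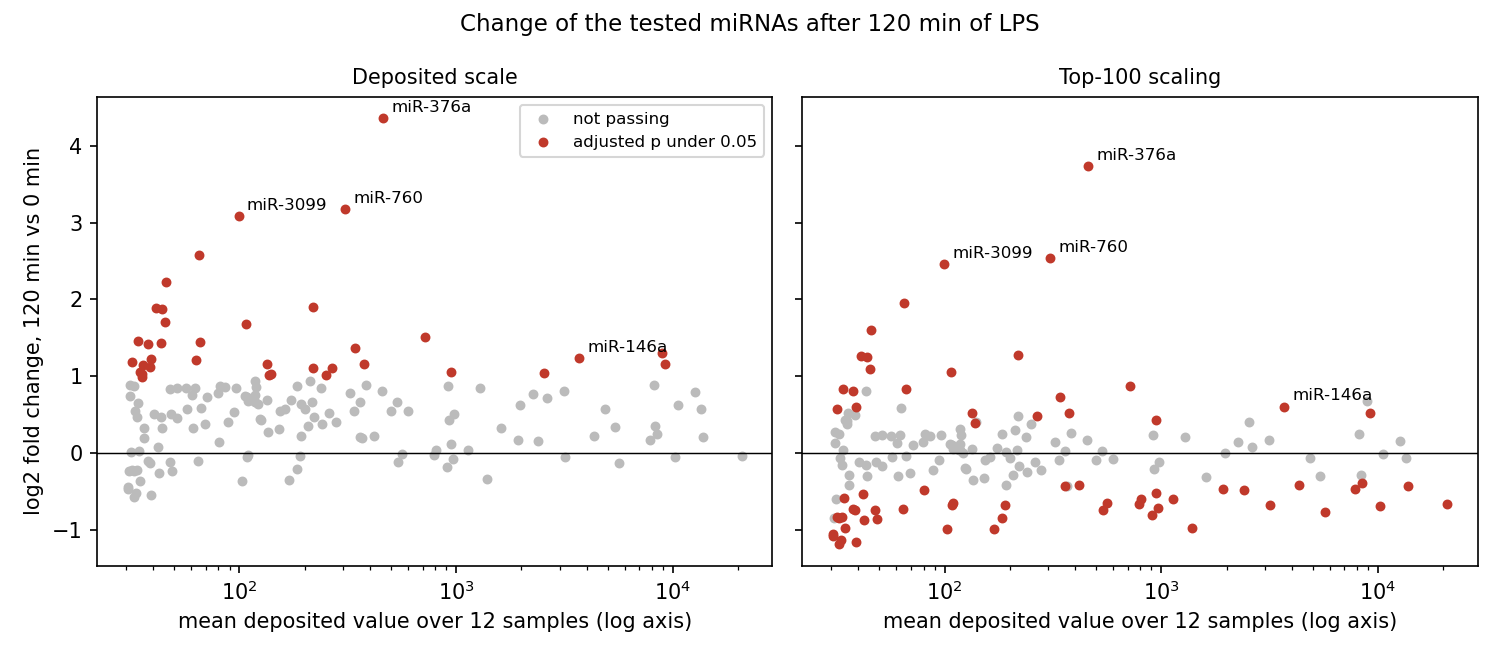
Each point is 1 of the 166 tested miRNAs, with its log2 fold change from 0 to 120 min of LPS against its mean signal over the 12 samples (log axis), on the deposited scale at left and after top-100 scaling at right; red marks an adjusted p under 0.05. The deposited scale has 36 red points above 0 and 0 below, and top-100 scaling 24 above and 45 below, with miR-376a highest in both panels.

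MiRNAs known from LPS responses were few in this panel's detectable range. Of the 8 probes matching the LPS-induced list, miR-155, miR-147, miR-212 and miR-9 lay at the floor in all 12 samples, and miR-146b and miR-187 lay below the filter (means of 30.3 ± 16.5 and 20 ± 0 at 120 min). MiR-146a, a feedback inhibitor of Toll-like receptor signalling (chromosome 11, 43374397 to 43374461), had a signal of 2551 ± 812, 2770.4 ± 582, 3368 ± 860.2 and 6045 ± 2095 at 0, 30, 60 and 120 min. It rose at 120 min by a log2 change of 1.24 ± 0.38 (adjusted p = 0.00995, higher in 3 of 3 samples than in any 0 min sample), and by 0.60 ± 0.12 under top-100 scaling. It did not pass under ligation control scaling (0.48), without 0 min replicate 3 (1.03) or without 120 min replicate 1 (0.97). At 30 and 60 min its changes were 0.14 and 0.41 and did not pass; under ligation control scaling it was lower at 30 min (-0.67). MiR-132 had 65.3 ± 22.5 at 0 min and 87.5 ± 41.4 at 120 min and did not pass (0.37 on the deposited scale and -0.26 under top-100 scaling). Thus 1 of 2 tested members was higher at 120 min over all tested and 1 adjusted over the list alone, with 0 at 30 and 60 min. Under ligation control scaling 2 members were lower at 30 min. At 60 min 1, miR-132, was lower under top-100 scaling and under ligation control scaling. MiR-21, named outside that list and at 120 min outside the naming rule, rose from 202 ± 43.1 to 463 ± 169 at 60 min (1.14 ± 0.38) and 475 ± 203.4 at 120 min (1.16 ± 0.38), with 0.67 and 0.53 under top-100 scaling. Its 120 min call ended without 0 min replicate 2, 0 min replicate 3, 120 min replicate 1 or 120 min replicate 2 (1.06, 1.09, 0.85 and 1.15).

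**Figure D3:**
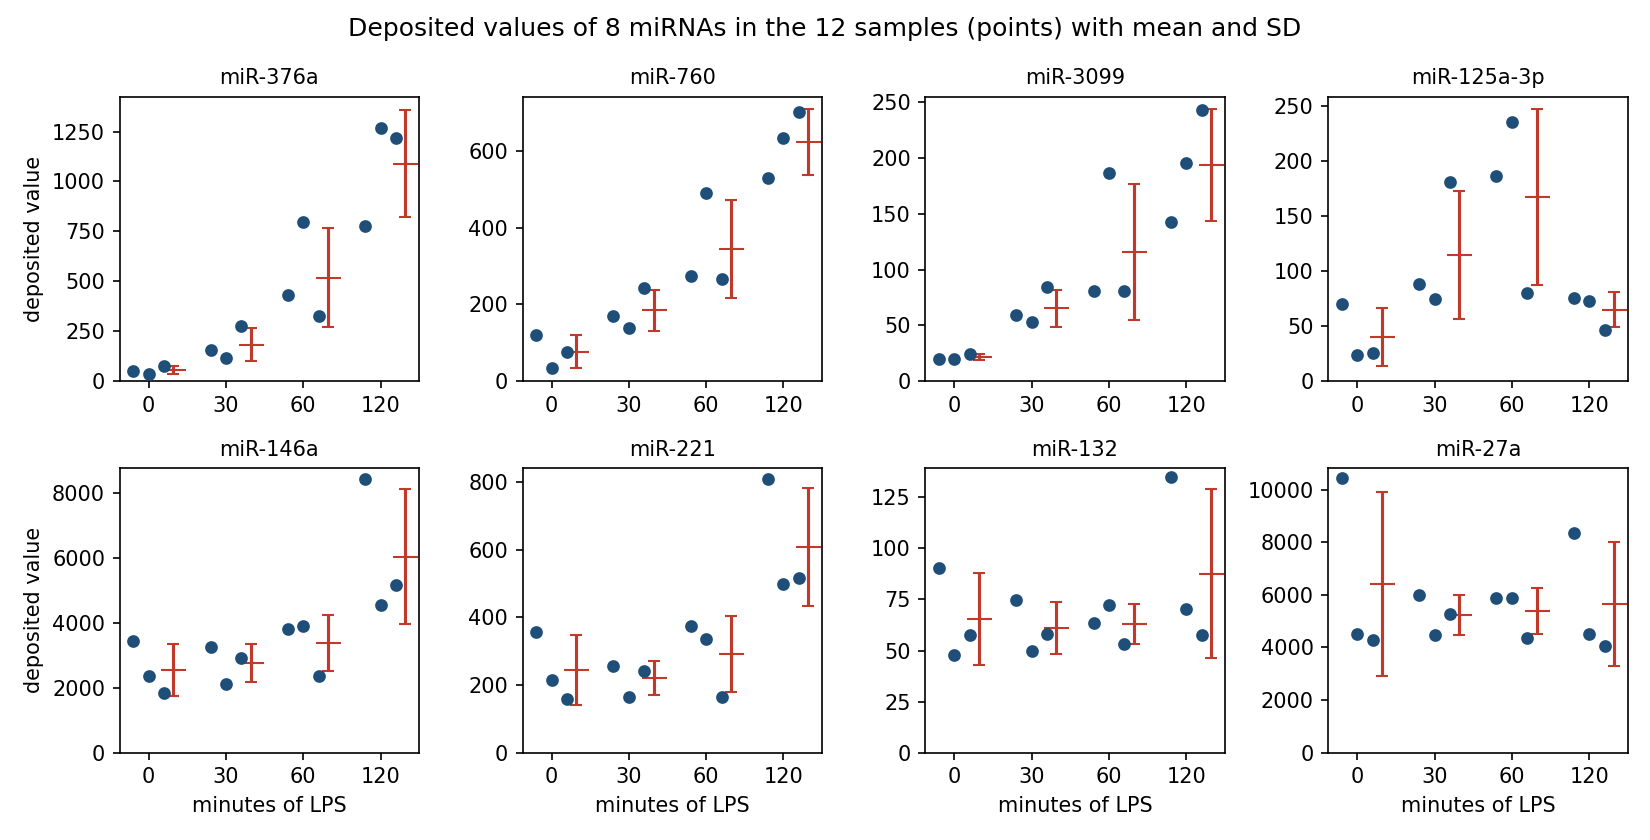
Deposited signal of 8 miRNAs in each of the 12 samples (points) against minutes of LPS, with the mean ± SD in red. MiR-376a, miR-760 and miR-3099 have their highest means at 120 min (1089, 623 and 193.7) and miR-125a-3p at 60 min (167); miR-27a has 6407 at 0 min and 5645 at 120 min, a change that did not pass on the deposited scale and passed as lower under top-100 and ligation control scaling.

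Myeloid miRNAs were mixed at 120 min. MiR-142-3p (10701 ± 6704, log2 change 1.31 ± 0.38), miR-146a and miR-16 (from 5607 ± 1328 to 12669.8 ± 3997, 1.16 ± 0.38; 0.52 under top-100 scaling) were higher, which makes 3 of 9 tested members over all tested and 3 adjusted over the list alone. The 9 leave out miR-21, which passed at 120 min and was meant for this list but did not match by name. MiR-223, a regulator of granulocyte function named outside the naming rule, had 848 ± 346 at 0 min and 1207 ± 487.3 at 120 min and did not pass (0.51). Under top-100 scaling 2 members were higher and miR-142-5p was lower, and camera gave adjusted p = 0.946 (0.986 with an estimated correlation). MiR-142-3p ended without 0 min replicate 3 (1.02) or 120 min replicate 1 (0.83), and did not pass under top-100 scaling (0.67). MiR-16 ended without 0 min replicate 2 or 3 or 120 min replicate 1 (1.06, 1.07 and 0.91). MiR-221 and miR-222, which share a precursor transcript and act on the cell cycle, both passed as higher at 120 min on the deposited scale. MiR-222, at the floor in all 0 min samples, had a change of 0.08 under the common floor (adjusted p = 0.569) and -0.54 with top-100 scaling added. That negative value follows from dividing floored entries by unlike sample factors. MiR-221 rose from 243 ± 103 to 607 ± 174 (1.37 ± 0.38; 0.73 under top-100 scaling), and its call ended without 0 min replicate 3 (1.10). That made 2 of 2 over all tested and 2 adjusted over the list alone.

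Among the growth-related families, the let-7 family had 0 of 9 members passing at 120 min, over all tested or adjusted over the list alone. Let-7a had 9759 ± 2667 at 0 min and 16696 ± 3921 at 120 min (0.79), and let-7g 13857 ± 6138 and 15605 ± 5464 (0.21). Under top-100 scaling 4 of the 9 were lower, let-7g among them (-0.43), so its direction flips with the scaling. For miR-17~92 and its paralogs 2 of 9 members were higher, and 2 adjusted over the list alone, namely miR-92a (0.31 under the common floor, not passing there) and miR-106b (562 ± 125.7 to 1201 ± 436, 1.06 ± 0.38; 0.42 under top-100 scaling). MiR-106b ended without 0 min replicate 2 or 3 or 120 min replicate 1 or 2 (1.02, 0.93, 0.78 and 1.15). The probe for miR-20a and miR-20b had a change of -0.03 on the deposited scale, and was lower under top-100 scaling (-0.67 ± 0.16). Of the miR-15/16 family 1 of 4 (miR-16) was higher, and 1 adjusted over the list alone. Of the miR-23/27/24 clusters 1 of 5 was higher, miR-24 (85.9 ± 20.2 to 176 ± 48.9, 1.01 ± 0.38; 0.38 under top-100 scaling), and 1 adjusted over the list alone. Its call ended without 0 min replicate 2 or 3 or 120 min replicate 1 or 2 (0.88, 0.97, 0.80 and 1.07). MiR-23a and miR-27a had changes of 0.22 and -0.13 on the deposited scale, and both were lower under top-100 scaling (-0.41 and -0.77). In the miR-99b, let-7e and miR-125a group 0 of 7 passed over all tested and 4 adjusted over the list alone, with miR-99b (138.03 ± 39.4 to 249.8 ± 44.8) at 0.88 and miR-99a at 0.03 (-0.60 under top-100 scaling). The miR-29 family (3 members), the miR-30 family (5) and miR-181 (1) had 0 passing at 120 min by either adjustment, and under top-100 scaling 1, 2 and 1 of them were lower. At 60 min miR-29b, chosen after its values were seen, passed (1.09 ± 0.38), though not under top-100 scaling (0.62), which made 1 of 3 and 2 adjusted over the list alone. That call ended without any one of 0 min replicates 2 and 3, 30 min replicates 1 and 3, 60 min replicates 1 and 2 and 120 min replicate 2, with 0.72 the lowest value. Camera passed for none of these families at any time point, with adjusted p from 0.157 to 0.972 (each 0.986 with an estimated correlation).

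The Dlk1-Dio3 cluster, a large imprinted miRNA locus, was represented by 52 probes, of which 30 lay at the floor in all 12 samples and 3 were tested. MiR-376a and miR-136 (121.8 ± 30.8 to 260.2 ± 32.3 at 120 min, 1.11 ± 0.38) were higher at 120 min, and miR-539, the third tested member (21.3 ± 2.18, with 2 of 3 samples at the floor, to 40.3 ± 5.15), did not pass. Over all tested 1, 2 and 2 of the 3 members passed at 30, 60 and 120 min, and 2, 2 and 3 adjusted over the list alone. The third of these at 120 min, miR-539, had no change under the common floor. Under top-100 scaling 0, 2 and 1 passed, with miR-136 not passing at 120 min (0.48). Camera passed for this list alone, at adjusted p = 0.0417, 0.00271 and 0.00271, with adjusted p = 0.986, 0.572 and 0.572 with an estimated correlation. Fry gave adjusted p = 0.129, 0.00799 and 0.00327, and under top-100 scaling camera gave 0.271, 0.150 and 0.176. The list call rests on 3 miRNAs, and without 60 min replicate 2, 120 min replicate 1 or 120 min replicate 2 the list had under 3 members past the filter and was not tested. With the same miRNAs kept in the test, an alternative chosen after seeing the data, the list passed at 60 and 120 min without any one library. It did not pass at 30 min without 0 min replicate 1, 0 min replicate 2 or 30 min replicate 3 (adjusted p = 0.170, 0.164 and 0.143). MiR-136 ended at 120 min without 0 min replicate 2 or 3 or 120 min replicate 1 or 2 (0.93, 1.11, 1.06 and 1.05). In the Sfmbt2 cluster, a rodent repeat of miRNA genes, 4 of 18 tested members were higher at 120 min and 4 adjusted over the list alone, while top-100 scaling gave 2 higher and 5 lower. Examples are miR-466h, miR-669f (1589 ± 602 to 3213 ± 1162, 1.04 ± 0.38; 0.40 under top-100 scaling, not passing) and the probe for miR-467h, miR-669d and miR-669l (1.15 ± 0.38; 0.52). The last 2 ended without 0 min replicate 2, 0 min replicate 3 or 120 min replicate 1, with lowest values of 0.69 and 0.96, and miR-669f also without 120 min replicate 2 (1.08). Camera for this cluster gave adjusted p = 0.946 at 120 min (0.986 with an estimated correlation).

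Few markers of other cell types passed the filter, and of those tested 0 passed at 120 min on the deposited scale. Of 10 epithelial probes 3 were tested and 0 passed on the deposited scale or adjusted over the list alone. MiR-200b had 32.8 ± 11.1 at 0 min and 22.8 ± 4.90 at 120 min, and miR-200c 36.6 ± 17.3 and 26.1 ± 10.6. Under top-100 scaling all 3, miR-192 included (-0.59), were lower at 120 min, where miR-200b and miR-200c each had 2 of 3 samples at the floor. That scaling divides floored entries by unlike sample factors, so for miR-200b and miR-200c the lower value is no clear evidence of a fall. Of 9 mesenchymal and endothelial probes 3 were tested and 0 passed by either adjustment. MiR-126-3p, typical of endothelial cells, had 205.7 ± 90.6 at 0 min and 160.1 ± 68.3 at 120 min (-0.35; -0.99 under top-100 scaling), and miR-199a-3p 598.7 ± 310.0 and 574.5 ± 231.3 (-0.01; -0.65 under top-100 scaling); these 2 of the 3 were lower under that scaling. Camera gave adjusted p = 0.157 and 0.668 for these lists at 120 min (both 0.986 with an estimated correlation). Camera compares a list with the other tested miRNAs, and its direction at 120 min was down while the median change was positive for the let-7, miR-15/16, miR-23/27/24, miR-29 and miR-30 families and the Sfmbt2 cluster. For the mesenchymal and endothelial list the mean was 0.10 and the median -0.01. The neural list had 2 tested members of 11, miR-128 and miR-132, and 0 passed by either adjustment. None of the 4 lymphoid and erythroid, 7 muscle, 1 liver, 16 stem cell and 5 stress-related probes passed the filter. Of these, miR-208b (muscle) lay at the floor in every earlier sample and had 61.2 ± 13.5 at 120 min, with 3 of 3 samples above 45.3. MiR-486 (erythroid), miR-292-5p and miR-293 (both stem cell) lay at the floor in all 0 min samples and above it in 3 of 3 at 120 min. Their means there, 42.4 ± 9.32, 35.6 ± 8.14 and 30.9 ± 10.8, lie within the 45.3 that the floor can hide. These 4 were not tested and were named after their values were seen.

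Between stimulated time points, with no shared control, the question was which miRNAs went on changing. From 30 to 60 min 1 miRNA passed in limma: miR-376a rose from 180.9 ± 83.1 to 516 ± 248 (1.50 ± 0.38, adjusted p = 0.0127, higher in 3 of 3 samples than in any 30 min sample). An unadjusted p under 0.05 was reached by 5. The call ended without 30 min replicate 1, 30 min replicate 2, 60 min replicate 1 or 60 min replicate 2 (1.43, 1.22, 1.58 and 1.13) and under top-100 scaling (1.37), and ligation control scaling gave 2 higher.

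From 60 to 120 min 0 miRNAs passed in limma on the deposited scale, and 15 had an unadjusted p under 0.05. MiR-146a had 3368 ± 860.2 and 6045 ± 2095 at these times (0.83 ± 0.38), miR-221 291.96 ± 112 and 607 ± 174 (1.10 ± 0.38), and miR-22 1197 ± 174 and 2157 ± 765 (0.80 ± 0.38). MiR-125a-3p went the other way, from 167 ± 79.6 to 64.8 ± 16.1 (-1.25 ± 0.38, adjusted p = 0.102). Top-100 scaling, whose median SE was 0.17, gave 4 higher, namely miR-146a (0.66), miR-221 (0.94), miR-22 (0.64) and miR-2146 (0.99), and 1 lower, miR-125a-3p (-1.41). These were named after their values were seen. Ligation control scaling gave 9 higher and 1 lower. The count on the deposited scale was 7 (6 higher and 1 lower) without 0 min replicate 1. It was 3 (1 higher and 2 lower) without 60 min replicate 3 or without 120 min replicate 1. It was 2 without 60 min replicate 2 and 1 without 0 min replicate 2 or 3 or any one of the 30 min replicates.

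Asked whether a miRNA differed at any time from 0 min, the moderated F test passed for 24 of 166 miRNAs, with 40 at an unadjusted p under 0.05. MiR-376a, miR-760 and miR-3099 were among them. Top-100 scaling gave 65 and ligation control scaling 93, and top-100 scaling gave 33 without 0 min replicate 1 and 36 without the first replicates of 0 and 120 min. The count was 52 without 0 min replicate 1 and 40 without 60 min replicate 3.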

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

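The tests of explanations for the median shift, for miR-376a and for the probes leaving the floor were chosen only after those results were seen, whereas the counts over other splits of the samples were planned.

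The median miRNA signal was higher after LPS on the deposited scale, by 0.32, 0.43 and 0.55 log2 units at 30, 60 and 120 min (per sample, the median difference of the tested miRNAs from their own means; SE 0.29, 0.34 and 0.36). The ligation controls, which the cells do not make, rose by 0.82, 0.82 and 0.76 on the same scale, at least as much as the miRNAs at 3 of 3 time points, which is consistent with a smaller ligation yield in the 0 min samples. Relative to the ligation controls the median was -0.50, -0.39 and -0.21 (SE 0.0941, 0.118 and 0.0967). At each time this negative value was larger against its SE than the positive value on the housekeeping scale. A rise of most miRNAs in the cells after LPS thus has a positive value on the housekeeping scale and a negative value on the ligation scale. It cannot be told apart from a difference in ligation. A loss of housekeeping mRNA after LPS cannot be told apart either. Housekeeping counts per positive control count changed by 0.17, 0.20 and 0.55 at 30, 60 and 120 min (SE 0.53, 0.55 and 0.56). Without 0 min replicate 1 they changed by -0.35, -0.33 and 0.03 (SE 0.11, 0.18 and 0.20). That library stands apart at 178.8 per 1000 against 544.8 and 513.7 in the other 0 min samples. A fall at 30 and 60 min thus appears only without it, and at 120 min, where the median shift was largest, there was none. The labels give no batch, so the order of processing could not be compared with the 0 min samples.

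MiR-376a rose at every time point, and from 30 to 60 min it is the 1 miRNA whose changes from 0 min differ by a test (log2 difference 1.50 ± 0.38, limma, adjusted p = 0.0127, higher in 3 of 3 samples). Over the alternatives its adjusted p ran from 0.000478 to 1. Transcription of the surrounding miRNA cluster may contribute, but 0 of the 5 probes of neighbouring genes lay above the floor in all 3 samples at 120 min. MiR-376c, miR-654-5p, miR-376b and miR-300 lay at the floor in all 12 samples. MiR-654-3p was above it in 8 of 12 samples, with a highest signal of 56.6, but in 1 of 3 at 0 min and 1 of 3 at 120 min. No neighbour thus showed a rise beside miR-376a. Another RNA induced by LPS and bound by the probe could also raise it, and the highest change of any viral probe was 1.09, against 4.37 for miR-376a. Both cannot be told apart, because the neighbours lie at or near the floor, where a rise from a low level stays hidden, the probe sequences are not given and the panel holds no other miR-376a probe.

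At 120 min 25 of the 399 probes that lay at the floor in all 0 min samples were above it in all 3 samples, and 0 probes went the other way. The 2 directions are not alike. To go the other way a probe had to reach 45.3 in 0 min replicate 1 and lie within 21.9, 20 and 20 in the 120 min samples. A small rise could suffice to leave the floor, so the 0 does not show that falls were absent. Of the 25, miR-691, miR-1970, miR-701, miR-208b and miR-92a alone exceeded 45.3 in all 3 samples at 120 min. A larger total signal of the 120 min samples may account for part of the 25. Total miRNA counts per positive control count rose by 1.01 log2 units (SE over libraries 0.254). The median least change of the 25 probes, against the most the floor can hide in each library, was 1.19, with 15 of them above the total change. Its error of 0.118 comes from the spread over probes of the same libraries, so it is not like the SE over libraries. Another RNA bound by the probes might do the same to viral probes, of which 2 were among the 25 and 1.63 would be by their share (Fisher's exact test, two-sided, p = 0.673). Neither explanation, nor expression of these miRNAs after LPS, can be excluded. The changes of 1.19 and 1.01 lie close together without errors of a like kind, and the viral probes are few.

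Among 42 probes outside the comparisons, 9 pairs of a probe and 1 of the 3 stimulated time points had all 3 stimulated samples above every 0 min sample, against 1.25 expected over all 20 orders of the 6 samples. The mean signal of LIG_POS_A was 8489 at 30 min, where the highest 0 min sample had 6058. LIG_POS_B had 1655 at 30 min and 1511 at 120 min, with 1282 as the highest at 0 min. LIG_POS_C had 154.9, 172.6 and 182.7 at 30, 60 and 120 min, with 106.4 as the highest at 0 min. The viral probes mcmv-miR-m01-2 (28.4 at 30 min), mcmv-miR-m88-1 (43.8 at 120 min) and mghv-miR-M1-7-5p (42.2 at 120 min) were at the floor in every 0 min sample, and their means lie below the 45.3 that the floor can hide there.

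For each comparison of 3 against 3 samples the 10 possible splits never allow a share under 0.05. At 30 min the real split gave 5 miRNAs and the highest other 2, and 1 of 10 splits gave as many. At 60 min the real split gave 18 and the highest other 83, with 2 of 10 giving as many, which points to a structure of the samples besides time. At 120 min the real split gave 36 and the highest other 2 (1 of 10). From 30 to 60 min the real split gave 1 and the highest other 2 (3 of 10), and from 60 to 120 min 0 and 10 (10 of 10). For the F test, 4 of 100 drawn splits, the real one included, gave as many as the real 24, with 37 the highest other. In a draw of 100 this share lies too near 0.05 to exclude chance. With top-100 scaling only the real split of the 100 did, with a real value of 65 and 8 as the highest other. Chance can be excluded there at a share of 0.05. For the list tests 9 of 100 gave as many as the real 3, with 3 as the highest other, and chance cannot be excluded.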

How the results depend on the processing

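Ligation control scaling, the common floor, the common floor with top-100 scaling, the fits without 0 min replicate 1 under top-100 scaling or without both first libraries of 0 and 120 min, the list tests with a fixed set of miRNAs, and the summed signal without each library were tests chosen only after the results were seen. The counts below are miRNAs passing at an adjusted p of 0.05 in limma, given as higher/lower where both occur. Apart from the scalings, which move all miRNAs of a sample together, and the filters, which change how many miRNAs are tested, the cause was not tested.

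At 30 min, where 5 miRNAs passed, eBayes with trend and robust estimation and the fit with only the 2 time points gave 5, a pseudocount of 10 gave 6, quantile normalization 6 (2/4) and the replicate block 7. No filter gave 0 and the filter at a mean of 100 gave 2. Top-100 scaling gave 1 (0/1), median scaling 20 (1/19), ligation control scaling 81 (2/79), the common floor 0 and the common floor with top-100 scaling 1 (0/1). Top-100 scaling without 0 min replicate 1 gave 0, and without both first libraries 0. Leaving out each library in turn gave 0 to 6, with 0 without 0 min replicate 2 or 30 min replicate 3 and 3 without 30 min replicate 1.

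At 60 min, where 18 passed, no filter gave 0, the filter at 100 gave 9, top-100 scaling 52 (19/33), quantile normalization 53 (22/31), median scaling 51 (8/43) and only the 2 time points 10. Ligation control scaling gave 69 (7/62), the common floor 2, the common floor with top-100 scaling 46 (14/32), and the fit without both first libraries 64. Top-100 scaling gave 23 (9/14) without 0 min replicate 1 and 23 (9/14) without both first libraries. Leaving out each library gave 7 to 41. The values that moved most were 38 without 0 min replicate 1, 41 without 60 min replicate 3, and 10, 9, 10 and 7 without 0 min replicate 2, 0 min replicate 3, 60 min replicate 1 and 60 min replicate 2.

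At 120 min, where 36 passed, the filter at 100 gave 18, top-100 scaling 69 (24/45), quantile normalization 57 (23/34), median scaling 64 (18/46), ligation control scaling 63 (15/48), the common floor 15, and the common floor with top-100 scaling 63 (15/48). Top-100 scaling gave 46 (18/28) without 0 min replicate 1 and 40 (18/22) without both first libraries. No filter gave 24 and only the 2 time points 25. Leaving out each library gave 16 to 81, with 81 without 0 min replicate 1, 21 without 0 min replicate 2, 19 without 0 min replicate 3 and 16 without 120 min replicate 1.

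The replicate block, which pairs samples of the same replicate number, gave 39 (39/0) at 60 min, 61 at 120 min, 6 (5/1) from 60 to 120 min, 40 in the F test, 1 from 30 to 60 min and 3 list tests. In the residuals same-number pairs had a median correlation of 0.05 and other pairs of -0.01. That correlation cannot see a sample-wide level shared by number. The factor of top-100 scaling was highest in replicate 1 at 0, 30 and 120 min (1.13, 1.11 and 1.71). At 60 min it was highest in replicate 2 (1.31 against 1.20 in replicate 1). Whether the numbers pair the samples was therefore not settled, and the planned unpaired fit was kept.

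From 30 to 60 min, where 1 passed, no filter gave 0, top-100 scaling 0, quantile normalization 0, median scaling 0, the common floor 0, the common floor with top-100 scaling 0, top-100 scaling without 0 min replicate 1 0 and without both first libraries 0. Ligation control scaling gave 2, and the deposited scale without both first libraries gave 2. Leaving out each library gave 0 to 1, with 0 without 30 min replicates 1 or 2 or 60 min replicates 1 or 2.

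From 60 to 120 min, where 0 passed and 15 had an unadjusted p under 0.05, no filter gave 7 (6/1), top-100 scaling 5 (4/1), quantile normalization 9 (7/2), median scaling 7 (6/1), ligation control scaling 10 (9/1), the common floor 1 and the common floor with top-100 scaling 4 (3/1). Top-100 scaling without 0 min replicate 1 gave 11 (7/4), and without both first libraries 12 (11/1). Leaving out each library gave 0 to 7, with 7 (6/1) without 0 min replicate 1 and 3 (1/2) without 60 min replicate 3 or 120 min replicate 1. It gave 2 without 60 min replicate 2 and 1 without 0 min replicate 2 or 3 or any 30 min replicate.

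In the F test, where 24 passed, no filter gave 12, the filter at 100 gave 9, top-100 scaling 65, quantile normalization 47, median scaling 56, ligation control scaling 93, the common floor 7 and the common floor with top-100 scaling 53. Top-100 scaling gave 33 without 0 min replicate 1 and 36 without both first libraries. Leaving out each library gave 18 to 52, with 52 without 0 min replicate 1 and 40 without 60 min replicate 3. A fit of only 2 time points gives no F test over all of them. Of the list tests 3 passed, and 0 passed with an estimated correlation, with no filter, with quantile normalization, with top-100 scaling or with ligation control scaling. Fry gave 2, and leaving out each library gave 0 to 4. The 4 without 0 min replicate 3 were 3 higher, from the Dlk1-Dio3 list, and 1 lower, from another list. The 0 without 60 min replicate 2, 120 min replicate 1 or 120 min replicate 2 is not a failed test: there miR-539 fell under the filter, and the Dlk1-Dio3 list, the 1 list that passed with all 12 libraries, was not tested (30, 30 and 33 tests in place of 36). With the 166 miRNAs of the full set kept, each of these 3 gave 3, and the others gave 2 to 4.

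Counting each named miRNA once per comparison gives 119 results, of which 55 passed on the deposited scale. Of 1458 pairs of a passing result and an alternative, 1058 kept the call and direction, 391 lost the call and 9 changed sign, and 7 results passed under every alternative that gave them a value. Of the 55, 15 passed with no filter, 52 with a pseudocount of 10, 36 under top-100 scaling, 35 under quantile normalization, 27 under median scaling, 55 with trend and robust estimation, 40 with only the 2 time points, 55 with the replicate block, 25 under ligation control scaling, 17 under the common floor and 24 under the common floor with top-100 scaling. The filter at 100 left 30 of them in the test and all 30 passed. For the 64 results that did not pass, a change of sign was counted as reversed only if it passed the threshold, a rule set after such changes were seen. Among their 1686 pairs, 44 reversed in this sense, 8.72% changed sign without passing, 169 passed in the same direction and 1326 stayed the same.

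The 9 passing results that changed sign did so under the common floor with top-100 scaling, and none passed as lower there. They were, on the log2 scale, miR-3471 (-0.00387), miR-701 (-0.26) and miR-2183 (-0.17) at 60 min, and miR-92a (-0.31), miR-3471 (-0.30), miR-301b (-0.31), miR-222 (-0.54), miR-101a (-0.43) and miR-500 (-0.60) at 120 min. Their mean signal at 0 min lies between 20 and 21.3, under the common floor of 45.3. In this setting the floor was set before the scaling, so entries at the floor differ by the sample factors alone. MiR-539, without a change under the common floor alone at 120 min, had -0.62 there. The 9 sign changes therefore reflect this offset of floored values and are no evidence of a reversal.

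Results that did not pass on the deposited scale with a positive change, and passed as lower under other scalings, were as follows on the log2 scale at 120 min. Under top-100, median, ligation control and common floor with top-100 scaling in that order, let-7g had -0.43, -0.51, -0.55 and -0.43, miR-99a -0.60, -0.69, -0.72 and -0.60, miR-15b -0.39, -0.48, -0.52 and -0.39, miR-23a -0.41, -0.50, -0.54 and -0.41, miR-29a -0.47, -0.55, -0.59 and -0.47, miR-181a -0.43, -0.51, -0.55 and -0.43, and the probe for miR-466a-3p and miR-466b-3-3p -0.48, -0.56, -0.60 and -0.48. MiR-192 had -0.59, -0.69 and -0.71 under the first 3 of these. Quantile normalization gave -0.29 for miR-99a, -0.45 for miR-23a, -0.43 for miR-29a, -0.50 for miR-181a and -0.40 for miR-192. Top-100 scaling without 0 min replicate 1 gave -0.61 for miR-99a, -0.40 for miR-23a, -0.52 for miR-29a and -0.54 for miR-192. Without both first libraries it gave -0.63 for miR-99a, -0.63 for miR-192 and -0.55 for the miR-466 probe. At 30 min miR-146a had -0.67 under ligation control scaling. These signs follow from the scalings, which lower the median of all tested miRNAs.

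The sum of miRNA signal differed from 0 min by 0.20, 0.28 and 0.43 log2 units at 30, 60 and 120 min, and the median in place of the sum by 0.49, 0.66 and 0.72. The sum without each library of the 2 time points differed by -0.00287 to 0.49, 0.08 to 0.57 and 0.17 to 0.72, with the lowest at 30 and 60 min without 0 min replicate 3, the lowest at 120 min without 120 min replicate 1, and the highest at each time without 0 min replicate 1. Depth limits the low end: 263 mouse miRNAs lay at the floor of 20 in all 12 samples, and in 0 min replicate 1 a floored entry can stand for up to 45.3. Alternatives made for raw counts, including scaling to the positive controls after subtracting the negative controls, were not run because the deposited values are normalized.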

Other observations

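The miRNAs in the first paragraph here were chosen only after their values were seen, and no explanation was tested for any value in this part.

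Several miRNAs outside the naming rule passed at 120 min in limma, higher on the deposited scale in 3 of 3 samples than in any 0 min sample unless said otherwise. MiR-107, a paralog of miR-103, rose from 163.9 ± 43.2 to 340.3 ± 136.4 (log2 change 1.01 ± 0.38 and 0.38 under top-100 scaling, not passing; adjusted p = 0.0357, from 0.00606 to 0.448 over the alternatives). Its call ended without 0 min replicate 2, 0 min replicate 3 or 120 min replicate 1 (0.82, 1.02 and 0.71). MiR-425 rose from 180.9 ± 61.4 to 388 ± 114 (1.11 ± 0.38, adjusted p = 0.0203, from 0.00171 to 0.168), and passed under top-100 scaling (0.47). Its call ended without the same 3 libraries (0.94, 1.01 and 0.88), and miR-191, from the same transcript, did not pass (0.84, adjusted p = 0.082). MiR-362-3p, higher in 2 of 3 samples than in any 0 min sample, rose from 83.8 ± 41.5 to 168 ± 68.8 (1.03 ± 0.38 and 0.40 under top-100 scaling, not passing; adjusted p = 0.0336, from 0.00127 to 0.330). That call ended without 0 min replicate 2, 0 min replicate 3, 120 min replicate 1 or 120 min replicate 2 (0.91, 0.77, 0.72 and 1.09). MiR-101a and miR-500, each with 2 of 3 samples at the floor at 0 min, rose from 21.1 ± 1.95 to 48.8 ± 11.9 and 44.8 ± 2.10. Neither passed under the common floor (0.19 and 0.02), and both changes turned negative with top-100 scaling added (-0.43 and -0.60). That sign reflects an offset of floored entries. MiR-101a ended without 0 min replicate 3 or 120 min replicate 1 or 2, and miR-500 without 0 min replicate 2 or 3 or any 120 min replicate.

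The geometric mean of the housekeeping mRNAs is fixed, so where some lie higher others must lie lower. Each of their differences between 0 and 120 min was smaller than the SD at 0 min, and none was tested. Actb had 21432 ± 4337 at 0 min and 23131 ± 436 at 120 min, B2m 6722 ± 1883 and 7313 ± 733, Gapdh 4923 ± 1060 and 4441 ± 785, and Rpl19 11633 ± 1168 and 10541 ± 1248. The spike-in probes ath-miR159a, cel-miR-248 and osa-miR414 lay at the floor in all 12 samples. Of the 3 negative ligation controls, LIG_NEG_A had 21.7 ± 2.92 at 60 min and the others lay at the floor in all samples.

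Late changes from 60 to 120 min that passed under top-100 scaling had wide ranges of adjusted p over their alternatives. The ranges were 0.00605 to 0.929 for miR-146a (log2 change 0.83 on the deposited scale, limma), 0.00195 to 0.776 for miR-221 (1.10), 0.00895 to 1 for miR-22 (0.80), 0.00605 to 0.716 for miR-2146 (1.16) and 0.00355 to 1 for miR-125a-3p (-1.25).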
